A study of Mus musculus with 11 samples.

How the data were processed

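Polyadenylated RNA was sequenced from the neocortex and the hippocampal CA1 region of mice carrying Camk2a-Cre and floxed Dicer, and from control mice. Per the labels' protocols, the neocortex libraries were made with a stranded mRNA kit and carried ERCC spike-in RNAs, and the CA1 libraries were made with an unstranded mRNA kit. The values used here are the deposited gene counts, whole numbers of reads per Ensembl gene identifier, with no normalization applied. The table held 39,109 entries, of which 92 were ERCC RNAs and 39,017 were genes. Per the submitters' processing notes, FastQC, GSNAP, SAMtools and bedtools were used with the mouse build GRCm38. The versions and roles of these tools, the counting rule, the annotation release and the strand setting of the counting were not given in the sources used here. Genes that share sequence with close relatives (C4b, the H2 genes, the protocadherins and Olfr78 among those named) are uncertain to the extent that the counting split or dropped such reads. In the unstranded CA1 libraries, reads of overlapping or antisense genes cannot be told apart.

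Gene symbols and positions came from GENCODE release M21, on GRCm38, by gene identifier. A match was found for 37,693 of the 39,017 identifiers (96.6%), and unmatched identifiers held at most 0.469% of a library's reads. The 11 libraries came from 7 animals, and 4 animals (D5130, D5133, D5134 and D5135) gave both tissues. Gene counts summed to between 43,144,097 and 58,329,441 per neocortex library and to between 24,806,581 and 35,684,618 per CA1 library. Mitochondrial genes took 5.97% to 6.57% of the reads in the neocortex and 4.52% to 4.97% in the CA1. The 10 genes with the most reads took 6.81% to 7.40% and 5.19% to 6.28%. Genes named as antisense took 0.114% to 0.118% and 0.695% to 0.707%.

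The comparisons, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except for those stated below to have been added later. Knockout (KO) and control libraries were compared within each tissue with edgeR 4.0.16 in R 4.3.3, because kit and run differed between the tissues. Library sizes were scaled by TMM, genes were kept by filterByExpr, and a quasi-likelihood F-test with robust dispersion was applied. P-values of these tests are two-sided, and adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. The standard error (SE) of a log2 fold change was its absolute value divided by the square root of F. CPM values (edgeR's cpm) use the TMM-scaled library sizes. The difference between the KO effects of the tissues was tested as an interaction in 1 fit of the 11 libraries with 4 group means. Counts were not corrected for gene length or C and G content.

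A total of 39 gene lists covered the miRNA pathway, targets reported for single miRNA families, cell types, glial reactions, neuronal activity and synapse genes, and housekeeping pathways. They were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided and adjusted over the lists. Camera with an estimated correlation and fry were the alternatives. A list counts as called here on the preset value, and the value with an estimated correlation is given beside it.

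The genes named in the text follow a rule. Dicer1 and the miRNA machinery list came first. In each tissue, the 12 genes with the largest rise and the 12 with the largest fall were then taken among genes past the threshold with a mean of at least 1 CPM and no overlap between KO and control libraries. Sex-linked genes, predicted genes and clone names were left out. For each list described, up to 4 members with the smallest p were named. For the interaction, 6 genes of each sign with the smallest p were named, which is how "6 of either sign" was read. Some genes that the rule takes are not reported here by name, and counts of genes include them. Genes named outside this rule are stated to have been picked afterwards.

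Whether animals pair the tissues was checked from the labels and the data. The labels give the same animal name for both tissues of 4 animals. The deviation of a library from its group mean correlated across genes between the neocortex and CA1 of the same animal with r of 0.199, 0.231, 0.213 and 0.364, against -0.403 to 0.174 between different animals of a genotype. Centring on group means fixes part of this contrast in advance, since the 2 CA1 KO libraries then have exactly opposite deviations. Following the labels, animal was fitted as a block as an alternative to the interaction test. No 2 libraries of a group were copies of each other, since their counts differed with a chi-square per gene of 9.46 to 20.6, where resequencing of 1 library would give about 1.

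For the miRNA sites, the 3′ UTRs of protein-coding transcripts were taken from GENCODE M21, and 14,774 genes in the neocortex and 14,958 in the CA1 had one. The mean log2 fold change of genes with an 8mer site of a family, less that of genes without it, was ranked among other 8mers ending in A with as many C and G bases and at least 50 genes. P-values were two-sided and adjusted over 20 families. A per-library version used an exact permutation test, whose smallest possible p is 0.1 in the neocortex and 0.2 in the CA1, so it cannot pass 0.05. These steps used Python 3.11.15 with numpy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.

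The alternatives were DESeq2 1.42.0, RLE size factors, no expression filter beyond 1 read, each library left out in turn, 1 fit of all libraries, male CA1 libraries alone, scaling by the ERCC counts and the animal block. The ERCC RNAs parted the neocortex libraries into 2 sets, which was found in the data. A batch term for these sets and each set alone were therefore added after the data were seen. So were 3 other settings of the miRNA site test and fry for the interaction.

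Each procedure was tested on simulated data with 200 changed genes of known fold. In the neocortex design, edgeR recovered 85.9% of genes changed 2-fold and 71.1% of those changed 1.5-fold. In the CA1 design it recovered 73.5% and 53.0%, and in the interaction design 63.3% and 46.5%. The share of calls that were false was 9.42%, 12.2% and 6.45% in these designs, above the nominal level. A list of 20 genes shifted by 0.5 log2 was called in each design by camera at either correlation, and with the preset correlation 1, 2 and 0 of the 39 other lists were called. Genes were simulated as independent, whereas the estimated correlation in the CA1 was 0.222 for activated microglia and 0.59 for oligodendrocyte genes. The simulation therefore does not measure the power or the false calls of camera for such lists. A shift of 0.1 log2 added to genes with a let-7 8mer was recovered as 0.102 in the neocortex (rank test adjusted p = 0.0191) and as 0.0775 in the CA1 (adjusted p = 0.668), so the rank test missed an effect of that size in the CA1. Reads carry no molecular identifiers, so intervals and floors given for counts cover counting error only.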

Results

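Dicer, the RNase that processes miRNA precursors, was removed from forebrain excitatory neurons of mice by Camk2a-Cre, and RNA was sequenced from the neocortex and the hippocampal CA1 region at 13 to 14 weeks of age. The neocortex gave 3 control libraries (D5129, D5134 and D5135) and 3 KO libraries (D5130, D5132 and D5133), all from males. The CA1 gave 3 control libraries (D5134 and D5135, male, and D5138, female) and 2 KO libraries (D5130 and D5133, male). The labels do not give the genotype of the control animals. In the neocortex, gene counts summed to 54,159,235 in D5129, 43,144,097 in D5134, 46,899,932 in D5135, 53,187,259 in D5130, 50,537,255 in D5132 and 58,329,441 in D5133. In the CA1 they summed to 26,250,135 in D5134, 33,692,702 in D5135, 35,684,618 in D5138, 33,677,646 in D5130 and 24,806,581 in D5133. ERCC RNAs took 0.113% to 0.686% of the neocortex reads. By these RNAs, D5129, D5130 and D5132 formed set 1 and D5133, D5134 and D5135 set 2, and each set held both genotypes. D5129 is the lone control of set 1 and D5133 the lone KO library of set 2. Tests within a set assume that this lone library varies like the other group.

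The targeted gene was examined first. Dicer1 (chromosome 12, 104,687,742 to 104,751,952, GRCm38) was counted at 66.5, 59.3 and 62.4 CPM in the neocortex controls D5129, D5134 and D5135 and at 63.3, 59.0 and 60.6 CPM in the KO libraries D5130, D5132 and D5133. In the CA1 it was counted at 74.0, 68.7 and 75.2 CPM in the controls D5134, D5135 and D5138 and at 73.4 and 71.6 CPM in the KO libraries D5130 and D5133. Its log2 fold change was -0.042 (SE 0.062, edgeR adjusted p = 0.797) in the neocortex and -0.003 (SE 0.068, edgeR adjusted p = 0.988) in the CA1. The count covers the whole gene, so it does not test the loss of the floxed exon and cannot check the genotype labels.

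Partners of the miRNA pathway were examined next. Of 17 machinery genes tested in the neocortex, 5 rose, 0 fell and 12 did not pass, and 7 rose when adjusted over the list alone. The GW182 family members Tnrc6c, Tnrc6b and Tnrc6a, which recruit the deadenylases, rose by 0.54 (SE 0.085), 0.47 (SE 0.075) and 0.42 (SE 0.059) log2, with edgeR adjusted p of 0.0118, 0.0108 and 0.00602. The Argonautes Ago1 and Ago2 rose by 0.34 (SE 0.063) and 0.32 (SE 0.067), with edgeR adjusted p of 0.0164 and 0.0273. Drosha, at 0.025 (SE 0.050, edgeR adjusted p = 0.856), and the export receptor Xpo5, at 0.083 (SE 0.066, edgeR adjusted p = 0.571), did not pass. In the CA1, 2 of 17 rose, 15 did not pass, and 3 rose when adjusted over the list alone. Tnrc6c rose by 0.34 (SE 0.063, edgeR adjusted p = 0.00835) and Tnrc6a by 0.31 (SE 0.071, edgeR adjusted p = 0.0270). As a list the machinery stood higher in the neocortex (camera adjusted p = 1.51e-06, adjusted p = 0.295 with an estimated correlation) and in the CA1 (camera adjusted p = 0.0261, adjusted p = 0.351 with an estimated correlation). The calls depended on single libraries more than the effects did. Of the 5 neocortex calls, 4 passed without D5130, 2 without D5132 and 0 without D5133. Without D5133 the log2 fold changes were 0.274 to 0.517 against 0.322 to 0.540. They were 0.199 to 0.467 in spike-in set 1 and 0.416 to 0.616 in set 2. Every gene called in the neocortex had no overlap between KO and control libraries, so a rise in both sets was largely fixed in advance. Of the CA1 calls, 1 passed without D5134, 0 without D5138 and 0 without D5133.

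To ask which transcripts respond to loss of Dicer in the neocortex, KO and control libraries were compared gene by gene. The largest rises were taken among called genes with a mean of at least 1 CPM and no overlap. They included immune genes, the abundant Ankrd52 and Trak2, and others such as Ppl, Dlk1 and Ltbp2. Ankrd52 (chromosome 10, 128,377,115 to 128,408,704), a subunit of the phosphatase that acts on Argonaute, rose from 88.1 ± 9.55 to 193.6 ± 16 CPM (SD, n = 3 each), a log2 fold change of 1.14 (SE 0.083, edgeR adjusted p = 0.000409). Trak2 (chromosome 1, 58,900,449 to 58,973,430), an adaptor that links mitochondria to kinesin, rose from 264.6 ± 13.2 to 528 ± 57.6 CPM (SD, n = 3 each), or 1.00 log2 (SE 0.076, edgeR adjusted p = 0.000409). The integrin gene Itgax, which encodes CD11c, rose by 2.76 (SE 0.47, edgeR adjusted p = 0.0251), from 0.411 to 2.81 CPM. The chemokine Ccl6 rose by 1.62 (SE 0.21, edgeR adjusted p = 0.00602), the complement gene C4b by 1.19 (SE 0.17, edgeR adjusted p = 0.0119) and the inhibitory receptor Lag3 by 1.11 (SE 0.14, edgeR adjusted p = 0.00602). The cytoskeletal linker Ppl rose by 1.63, the Notch pathway ligand Dlk1 by 1.15, the matrix gene Ltbp2 by 1.12, and the chemokine Cxcl16 and the lysosomal peptide carrier Slc15a3 by 1.05 each.

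The falls were smaller. The proenkephalin gene Penk fell from 61.2 ± 10.2 to 35.1 ± 2.81 CPM (SD, n = 3 each), a log2 fold change of -0.80 (SE 0.12, edgeR adjusted p = 0.0136). The secreted Wnt antagonist Frzb changed by -0.79 (SE 0.15, edgeR adjusted p = 0.0251) and the growth factor Fgf10 by -0.63 (SE 0.14, edgeR adjusted p = 0.0326). The olfactory receptor Olfr78 changed by -1.51 and the tumour necrosis factor receptor family gene Tnfrsf8 by -1.33, both from under 2 CPM. Pgam2, a muscle-type glycolytic enzyme, changed by -0.71, the kinase Stk26 by -0.71, the vesicle gene Sytl1 by -0.69, the crystallin Crybb1 by -0.68, Tpd52l1 by -0.64, the kinesin Kif9 by -0.62 and the transcription factor Stat4 by -0.62.

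Across the neocortex 256 genes rose and 204 fell of 16,971 tested (2.71%, edgeR), against 3,049 genes at an unadjusted p under 0.05. Rises of over 1.5-fold numbered 53 and falls 20, and the median absolute log2 fold change of the called genes was 0.34. KO and control did not overlap in 24.0% of tested genes, where chance gives 10.0%. The count rested on few libraries, since 16 rose and 3 fell without D5133, 100 and 44 without D5132, 130 and 79 without D5130, and 133 and 74 without D5129. With the spike-in set as a batch term 122 rose and 69 fell. Each set alone leaves a lone library in a group (the control D5129 in set 1, the KO library D5133 in set 2), so effects are given for the sets here. Of the 24 genes taken for the largest changes, all 24 kept their direction in both sets. Taking only genes without overlap largely fixed this in advance, so it does not test the batch. Ccl6, Ankrd52, Lag3 and Trak2 passed whichever library was left out. Ankrd52 rose by 0.93 in set 1 and 1.31 in set 2, and Penk changed by -0.46 and -1.03. All directions are relative to the median gene. Scaling by the ERCC RNAs raised the median log2 fold change to 1.06 and left 4 genes higher and 0 lower (edgeR), with 583 at an unadjusted p under 0.05.

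The neocortex changes were then set against gene lists for cell types and pathways. Activated microglia genes were the most affected: 12 of 24 rose, 0 fell and 12 did not pass, and 16 rose when adjusted over the list alone. Besides Ccl6 and Itgax these included the lysosomal marker Cd68, at 0.73 (SE 0.11, edgeR adjusted p = 0.00760), the signalling adaptor Tyrobp, at 0.64 (SE 0.10, edgeR adjusted p = 0.00874), and the lipase Lpl, at 0.50 (SE 0.080, edgeR adjusted p = 0.00875). The count of 12 became 2 without D5133, 6 without D5129, 7 without D5132 and 8 without D5135, and it was 0 in set 1 and 7 in set 2. Homeostatic microglia genes did not pass (0 of 15 by edgeR, with 5 at an unadjusted p under 0.05, and 2 higher and 1 lower by DESeq2), and their median log2 fold change was -0.038. Among complement and antigen presentation genes 4 of 25 rose, and 8 rose and 1 fell when adjusted over the list alone. C1qb rose by 0.49 (SE 0.082, edgeR adjusted p = 0.0123) and the receptor C3ar1 by 0.85 (SE 0.16, edgeR adjusted p = 0.0199), and 0 passed without D5133, 1 without D5129 and 2 without D5132.

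Cholesterol synthesis genes fell in the neocortex, with 4 of 24 lower, 0 higher and 20 not passing, and 11 lower when adjusted over the list alone. Fdps changed by -0.44 (SE 0.070, edgeR adjusted p = 0.00874) and Mvk by -0.41 (SE 0.080, edgeR adjusted p = 0.0217). These calls became 0 without D5133, 1 without D5132 and 2 without D5129, and 0 in either set alone. Among reported miR-29 targets 4 of 20 rose, and 4 when adjusted over the list alone. The DNA methyltransferase Dnmt3a rose by 0.76 (SE 0.072, edgeR adjusted p = 0.00113) and the hydroxylase Tet1 by 0.64 (SE 0.12, edgeR adjusted p = 0.0152). The miR-29 count was 1 without D5133, 1 without D5132, and 2 without D5129 or D5130. Of genes with high expression in striatum 3 of 12 fell, among them Penk and Ppp1r1b at -0.28 (SE 0.061, edgeR adjusted p = 0.0346), with 0 left without D5133 and 1 without D5132 or D5134. In spike-in set 1 alone 0 of the striatum genes fell and 1 rose, in set 2 alone 1 fell, and with the batch term 2 fell and 1 rose. Their median of -0.355 became -0.042 without D5135. Of excitatory neuron genes 2 of 20 fell, the inositol phosphate kinase gene Itpka at -0.55 (SE 0.066, edgeR adjusted p = 0.00271) and the calmodulin-binding gene Nrgn at -0.37 (SE 0.065, edgeR adjusted p = 0.0151), with 1 left without D5132 or D5133. Oligodendrocyte genes did not pass (0 of 18 by edgeR, with 2 at an unadjusted p under 0.05, and 0 by DESeq2), nor did meninges genes (0 of 15 by edgeR, with 0 at an unadjusted p under 0.05, and 0 by DESeq2). Without D5135, 3 meninges genes rose and their median went from 0.141 to 0.597, so their number in the neocortex depends on that library. Immediate early genes did not pass in the pooled libraries (0 of 22 by edgeR, with 1 at an unadjusted p under 0.05, and 1 by DESeq2). Their median log2 fold change was -0.642 in spike-in set 2, where D5133 is the lone KO library. It was -0.031 in set 1, where D5129 is the lone control.

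With the preset correlation camera called 9 lists higher and 7 lower in the neocortex, activated microglia with an adjusted p of 1.12e-20 and cholesterol synthesis with 2.61e-10. With an estimated correlation 0 lists were called, and those 2 lists both had an adjusted p of 0.295. Fry called 0 lists as well. The 9 lists called higher at the preset correlation include the sex-linked one (camera adjusted p = 0.00425), of which 2 of 9 tested genes passed as higher. All neocortex libraries came from males, but the Y-linked genes of the control D5134 stood at 41.1% of the male median. Whether this library gave the call was not tested. Camera with the preset value also called 7 to 14 lists in the other 9 ways of splitting the 6 libraries into 3 and 3. Each of these splits keeps 2 KO libraries together, so part of a genotype effect stays in them, and which lists they called was not kept. Their number cannot show which list calls follow genotype. The counts of members past the gene test describe a list but do not test it, since members can vary together.

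**Figure D1:**
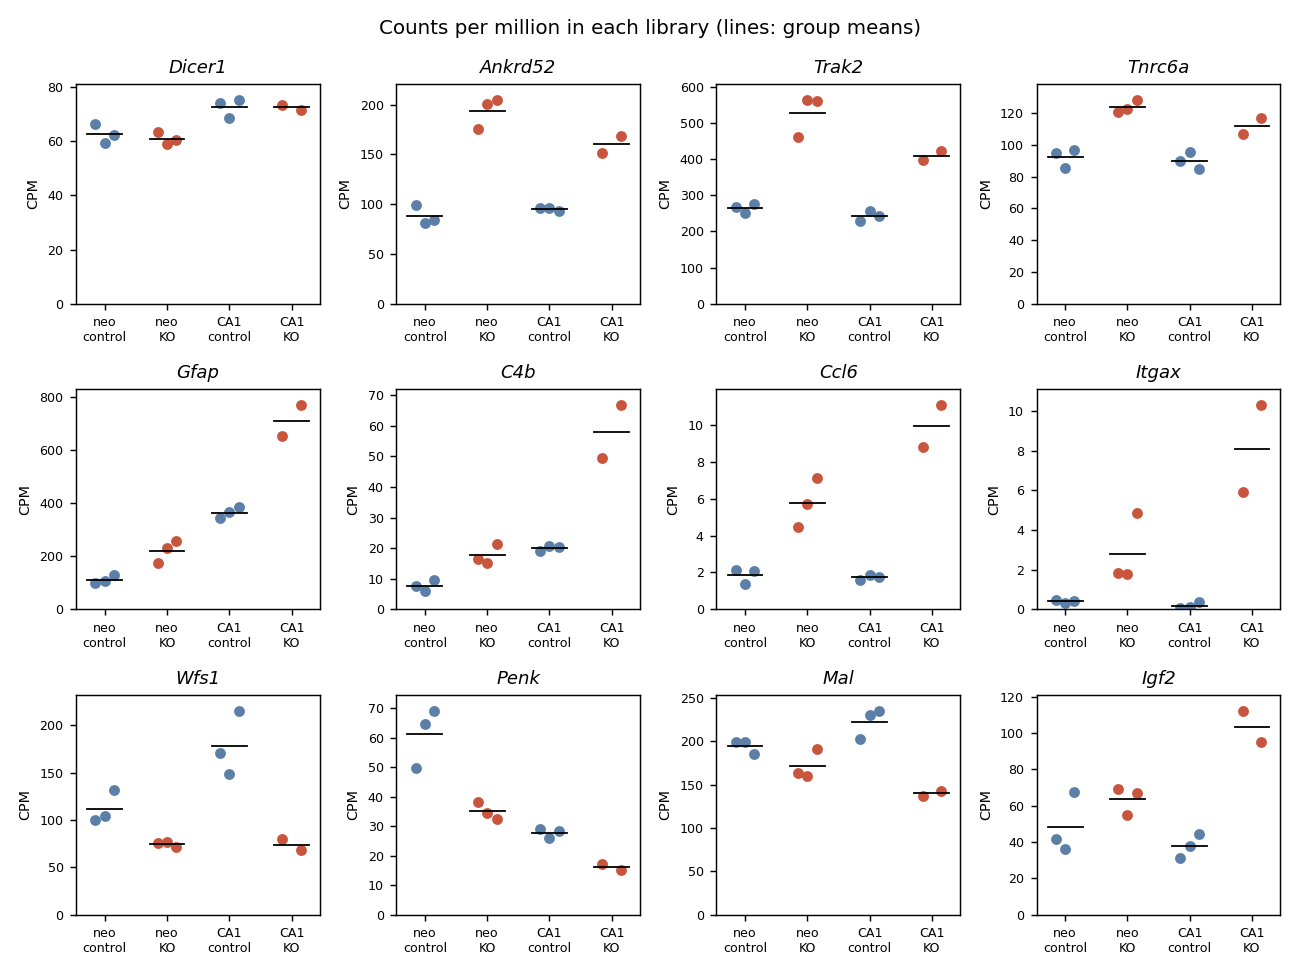
CPM (linear axis from 0) of 12 genes in each library, with points for libraries and lines for group means, in control and KO neocortex and CA1. Ankrd52 and Trak2 stood higher in every KO library of both tissues, Dicer1 overlapped in both, and Wfs1 and Penk stood lower in every KO library.

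The same comparison in the CA1 showed larger changes. Cst7 (chromosome 2, 150,570,415 to 150,578,944), a lysosomal protease inhibitor, rose from 0.0594 ± 0.0607 to 3.21 ± 0.816 CPM (SD, n = 3 and 2), a log2 fold change of 5.57 (SE 0.50, edgeR adjusted p = 3.83e-05). Itgax (chromosome 7, 128,129,547 to 128,150,656) rose by 5.31 (SE 0.41, edgeR adjusted p = 0.000103). Ccl6 rose from 1.74 ± 0.146 to 9.95 ± 1.59 CPM (SD, n = 3 and 2), or 2.51 log2 (SE 0.18, edgeR adjusted p = 1.10e-05). The class II antigen genes H2-Aa and H2-Ab1 rose by 2.74 (SE 0.43, edgeR adjusted p = 0.00332) and 2.28 (SE 0.42, edgeR adjusted p = 0.00824), and the sialic acid receptor Siglecf by 2.82 (SE 0.39, edgeR adjusted p = 0.00143). The protease Ctse rose by 3.80 (SE 0.37, edgeR adjusted p = 9.10e-05), and 2 subunits of the epithelial sodium channel, Scnn1b and Scnn1g, by 4.10 (SE 0.35, edgeR adjusted p = 2.67e-05) and 2.37 (SE 0.26, edgeR adjusted p = 0.000239). Ltbp2 rose by 2.62, Arhgap36, a protein kinase A antagonist, by 2.57 and Wnt6 by 2.40. Cst7, Itgax, Scnn1b and Ctse had under 0.2 CPM in the controls, so their folds rest on few control reads.

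Among the genes named, falls in the CA1 were smaller than rises. Wfs1 (chromosome 5, 36,966,104 to 36,988,933), which encodes an endoplasmic reticulum protein abundant in CA1 pyramidal cells, fell from 178 ± 33.8 to 74.1 ± 7.65 CPM (SD, n = 3 and 2), a log2 fold change of -1.26 (SE 0.18, edgeR adjusted p = 0.0261). The activity-regulated transcription factor Npas4 changed by -1.12 (SE 0.24, edgeR adjusted p = 0.0484), the peptide Apln by -1.04 (SE 0.11, edgeR adjusted p = 0.000234) and Enpp6, a gene of newly forming oligodendrocytes, by -1.18 (SE 0.19, edgeR adjusted p = 0.00357). Wnt2 changed by -1.68 (SE 0.21, edgeR adjusted p = 0.000682) and Wnt9a by -0.90 (SE 0.16, edgeR adjusted p = 0.00596). The troponin Tnnt2 changed by -1.76, Ankub1 by -1.26, the phospholipase-like gene Hrasls by -1.21, the potassium channel subunit Kcns1 by -0.88, the protocadherin Pcdhb2 by -0.84 and Samd5 by -0.83.

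In the CA1 452 genes rose and 258 fell of 18,274 tested (3.89%, edgeR), against 3,159 at an unadjusted p under 0.05. Rises of over 1.5-fold numbered 247 and falls 51, and the median absolute log2 fold change of the called genes was 0.51. KO and control did not overlap in 33.7% of tested genes, where chance gives 1 in 5. With the female control D5138 left out, 177 rose and 67 fell. Without D5133 149 rose and 83 fell, and without D5130 252 rose and 141 fell. A lone KO library left by these fits is assumed to vary like the controls. Of the 24 genes taken for the largest changes, 17 passed without D5138, 15 without D5133 and 18 without D5130, and 14 passed whichever library was left out.

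Lists of microglia, complement and reactive astrocyte genes had members that rose in the CA1. Of activated microglia genes 16 of 24 rose, 0 fell and 8 did not pass, and 21 rose when adjusted over the list alone, among them the lysozyme Lyz2, at 1.78 (SE 0.15, edgeR adjusted p = 2.18e-05). The count was 12 to 16 whichever library was left out. Of complement and antigen presentation genes 13 of 25 rose, and 18 when adjusted over the list alone. The complement subunits C1qa, C1qb and C1qc rose by 0.94 (SE 0.079), 1.05 (SE 0.070) and 1.04 (SE 0.079), with edgeR adjusted p of 2.18e-05, 9.55e-06 and 1.39e-05. The count of 13 became 6 without D5133. Of reactive astrocyte genes 10 of 23 rose, and 13 rose and 1 fell when adjusted over the list alone. The filament protein Gfap rose from 364.4 ± 20.8 to 710.3 ± 81.7 CPM (SD, n = 3 and 2), or 0.96 log2 (SE 0.070, edgeR adjusted p = 1.39e-05). The receptor Osmr rose by 1.03 (SE 0.19, edgeR adjusted p = 0.00757). The count of 10 became 3 without D5133, 5 without D5138 and 6 without D5130. In the neocortex Gfap changed by 0.99 (SE 0.18) without passing (edgeR adjusted p = 0.0620). Of general astrocyte genes 3 of 18 rose in the CA1, and 8 when adjusted over the list alone. In the neocortex 0 of 18 passed, and 3 rose when adjusted over the list alone. Of interferon response genes 4 of 22 rose in the CA1, and 8 when adjusted over the list alone, with 0 left without D5133, 1 without D5130 and 2 without D5134 or D5138. Of homeostatic microglia genes 4 of 15 rose, and 4 when adjusted over the list alone, among them Fcrls, at 0.72 (SE 0.094, edgeR adjusted p = 0.000932), with 1 left without D5133 and 2 without D5138. Of autophagy and lysosome genes 7 of 30 rose, and 7 when adjusted over the list alone, with the lysosomal protease Ctsd at 0.56 (SE 0.057, edgeR adjusted p = 0.000139). This count of 7 became 2 without D5133, 3 without D5138 and 4 without D5130 or D5135.

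Oligodendrocyte genes fell in the CA1: 12 of 18 were lower, 0 were higher and 6 did not pass, and all 18 fell when adjusted over the list alone. The myelin gene Mal fell from 222.5 ± 17.9 to 139.8 ± 4.50 CPM (SD, n = 3 and 2), or -0.67 log2 (SE 0.071, edgeR adjusted p = 0.000179). The tight junction gene Cldn11 changed by -0.59 (SE 0.069, edgeR adjusted p = 0.000413) and Ugt8a, which makes the galactolipids of myelin, by -0.68 (SE 0.098, edgeR adjusted p = 0.00225). Whether KO and control samples held like shares of oligodendrocytes was not tested. The count of 12 became 6 without D5133 and 7 without D5130. Among CA1 pyramidal genes 4 of 11 fell, and 9 when adjusted over the list alone. Besides Wfs1 these were the transcription factors Pou3f1, at -0.68 (SE 0.085, edgeR adjusted p = 0.000682), and Neurod6, at -0.56 (SE 0.081, edgeR adjusted p = 0.00253), and the mannosidase Man1a, at -0.65 (SE 0.12, edgeR adjusted p = 0.0151). The count was 3 to 4 whichever library was left out. Immediate early genes were lower in 21 of 22 cases, but 2 passed, Npas4 and the phosphatase Dusp6, at -0.82 (SE 0.098, edgeR adjusted p = 0.000731), and 3 when adjusted over the list alone. Without D5133 or D5138 1 passed, and without D5135 4.

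Meninges and fibroblast genes rose in the CA1, with 8 of 15 higher, 7 not passing and 11 higher when adjusted over the list alone. The growth factor Igf2 rose from 37.9 ± 6.54 to 103.4 ± 12.3 CPM (SD, n = 3 and 2), or 1.45 log2 (SE 0.14, edgeR adjusted p = 0.00210), and the matrix gene Ogn by 0.90 (SE 0.16, edgeR adjusted p = 0.00712). The count of 8 became 4 without D5130. Of the miR-29 targets 4 of 20 rose, and 9 when adjusted over the list alone: Dnmt3a, at 0.59 (SE 0.070, edgeR adjusted p = 0.000503), and the matrix genes Eln, at 1.02 (SE 0.14, edgeR adjusted p = 0.00143), Sparc, at 0.62 (SE 0.10, edgeR adjusted p = 0.0171), and Col1a2, at 1.30 (SE 0.19, edgeR adjusted p = 0.00844), which is also on the meninges list. Of miR-124 targets 6 of 24 rose, and 7 when adjusted over the list alone, including the splicing regulator Ptbp1, at 0.37 (SE 0.079, edgeR adjusted p = 0.0198). The miR-124 count became 0 without D5133, 1 without D5138 and 4 without D5134. Of cholesterol synthesis genes 3 of 24 fell, and 11 when adjusted over the list alone, with 0 left without D5133, 0 without D5138 and 5 without D5130.

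With the preset correlation camera called 13 lists higher and 9 lower in the CA1. The adjusted p was 3.24e-60 for activated microglia, 8.25e-40 for complement, 1.68e-15 for reactive astrocytes, 1.84e-26 for oligodendrocytes and 4.12e-13 for CA1 pyramidal genes. With an estimated correlation 0 lists passed, and the adjusted p was 0.0902 for activated microglia, complement and reactive astrocytes, 0.104 for CA1 pyramidal, meninges, miR-29 and interferon genes and 0.167 for oligodendrocytes. Fry called 9 lists higher and 2 lower.

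**Figure D2:**
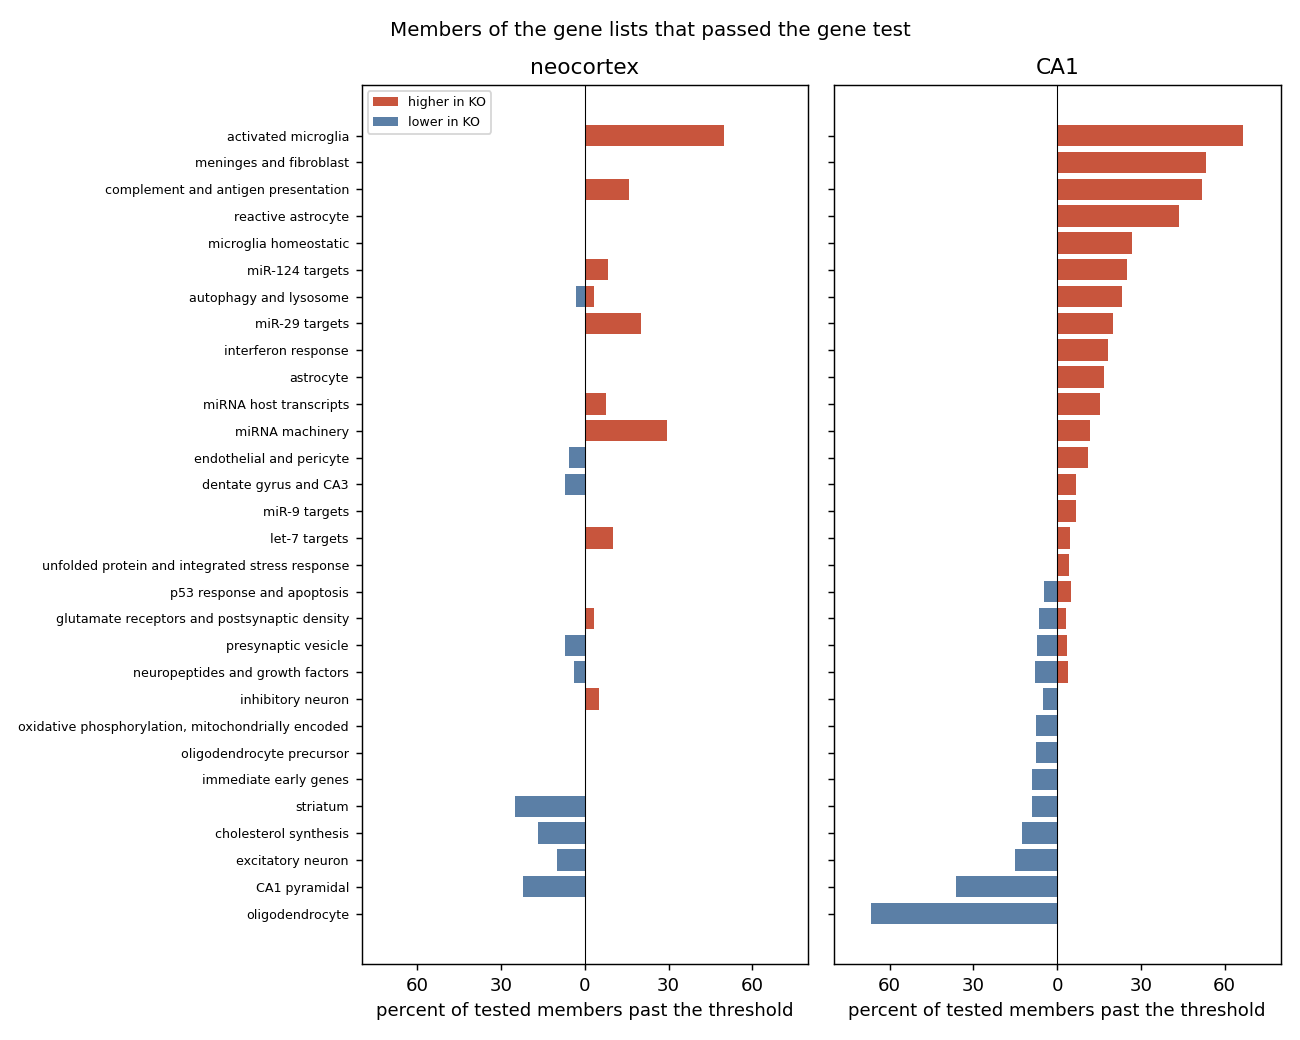
Percent of tested members of each gene list that passed the edgeR gene test, with bars to the right for genes higher in KO and to the left for genes lower in KO, in the neocortex and the CA1. In the CA1, 16 of 24 activated microglia genes were higher and 12 of 18 oligodendrocyte genes lower.

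To compare the tissues, the log2 fold changes of 16,544 genes tested in both were set against each other. Across genes, which are not independent replicates, Pearson's r was 0.313 and Spearman's rho 0.307. The neocortex effect from D5132 and D5129 alone, which gave no CA1 library, had r of 0.151 and rho of 0.195. That estimate has 1 library per group, so the smaller number of libraries and the lack of shared animals cannot be told apart in it. A total of 76 genes rose in both tissues, where independent lists give 6.81, and 23 fell in both, where they give 3.12, and 2 were called in opposite directions. The numbers for independent lists make no allowance for the 4 animals that gave both tissues. Of the genes called in the neocortex, 409 of 459 (89.1%) had the same sign in the CA1. Of those called in the CA1, 588 of 694 (84.7%) had the same sign in the neocortex, and 517 (74.5%) with the unshared animals. Wfs1 was lower in both, at -0.58 (SE 0.095) and -1.26 (SE 0.18), Penk at -0.80 (SE 0.12) and -0.76 (SE 0.10), and Ankrd52 rose in both, by 1.14 (SE 0.083) and 0.75 (SE 0.065).

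**Figure D3:**
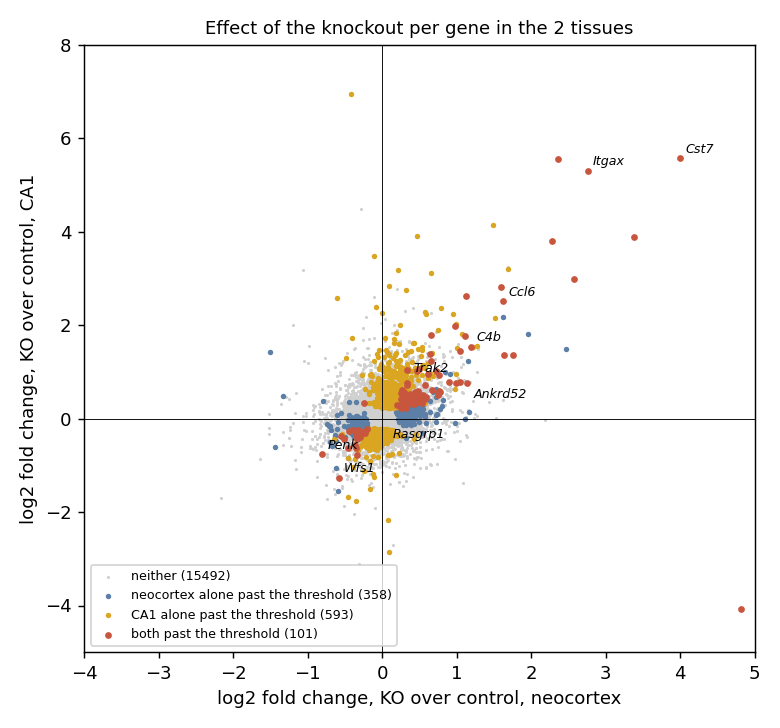
Log2 fold change of KO over control in the neocortex (horizontal) against the CA1 (vertical) for genes tested in both, coloured by which edgeR test they passed, with 1 gene outside the axes. The genes past both thresholds lie mostly in the upper right and lower left, with Cst7 and Itgax at the upper right.

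Whether the KO effect differed between the tissues was tested as an interaction. It was higher in the CA1 for 11 genes and lower for 7 of 19,256 (edgeR), with 1,831 at an unadjusted p under 0.05. Genes whose effect was higher in the CA1 included C1qc, with a difference of 0.71 (SE 0.10, edgeR adjusted p = 0.0246), and Lyz2, with 1.13 (SE 0.19, edgeR adjusted p = 0.0313), both higher in KO in both tissues. The thyrotropin-releasing hormone Trh differed by 2.74 (SE 0.41, edgeR adjusted p = 0.0284), the growth factor binding gene Igfbp2 by 1.05 (SE 0.17, edgeR adjusted p = 0.0313), the laminin Lamb2 by 0.56 (SE 0.096, edgeR adjusted p = 0.0313) and the vesicle transport gene Hap1 by 0.58 (SE 0.095, edgeR adjusted p = 0.0313). Hap1 changed by -0.25 (SE 0.059) in the neocortex and by 0.33 (SE 0.072) in the CA1. The effect was lower in the CA1 for the signalling gene Rasgrp1, by -0.59 (SE 0.078, edgeR adjusted p = 0.0144), which changed by -0.53 (SE 0.057) in the CA1 and by 0.062 (SE 0.050) in the neocortex. It was also lower for Arap2 (-0.47), the semaphorin receptor Plxna4 (-0.55), the ubiquitin ligase gene Fbxo32 (-0.66) and the receptor auxiliary gene Shisa7 (-0.39), with SE of 0.077, 0.092, 0.12 and 0.072. These calls were fragile: 0 of the 12 genes taken by the naming rule passed whichever library was left out. With a block for animal 36 genes were higher and 78 lower, and 10 of the 12 passed, while Shisa7 was among those that did not (edgeR adjusted p = 0.0532).

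As lists, complement, reactive astrocyte and CA1 pyramidal genes differed between the tissues at either correlation, with a camera adjusted p of 2.78e-18, 4.96e-07 and 9.16e-07 preset and an adjusted p of 0.0347 each with an estimated correlation. Camera called 10 lists higher and 5 lower with the preset value, and the estimated one called 2 higher and 1 lower. With a block for animal those 3 had a camera adjusted p of 0.467, 0.472 and 0.494 at an estimated correlation. With a term for each of 7 animals, that fit leaves little replication to estimate spread and correlation from. These values therefore cannot show that the difference is absent. At the preset correlation the 3 lists kept their camera call in all 14 alternative settings, the block among them. The activated microglia list (camera adjusted p = 2.48e-13) had an adjusted p of 0.0725 with an estimated correlation and the oligodendrocyte list (camera adjusted p = 1.89e-17) 0.111. Tissue, kit and sequencing run change together in this design, and they drop out of the difference only as far as they act on a gene's KO and control libraries alike.

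To look for loss of repression by single miRNAs, genes with and without seed sites in their 3′ UTRs were compared. In the neocortex genes with an 8mer site stood higher than those without. The difference was 0.057 (SE 0.009) log2 for let-7, 0.060 (SE 0.010) for miR-124 and 0.067 (SE 0.010) for miR-29. The SE of site differences is taken across genes, which are not independent replicates. Per library, KO less control was 0.0541, 0.0594 and 0.0621 for these families, with a control SD of 0.028, 0.0462 and 0.0485 (n = 3). Their exact permutation p was 0.1 each, the smallest possible. Other 8mers of like composition had a median difference of 0.027. Of the 20 families, 18 stood above the median of their control 8mers and 0 passed the rank test, whose lowest adjusted p was 0.293, and miR-29 had an unadjusted p of 0.0253. In the CA1 12 of 20 stood above the median and 0 passed, with a lowest adjusted p of 0.601 by exact rank among the control 8mers, and miR-29 differed by 0.036 (SE 0.016, unadjusted rank p = 0.0301). When families were ranked by the difference over its SE, an order chosen after this result, 7 passed in the neocortex and 1 in the CA1, miR-29 with an adjusted rank p of 0.0191. With this ranking and only genes of at least 1 CPM, 11 passed in the neocortex and 2 in the CA1. On residuals from 3′ UTR length, base composition and expression over those genes, with the same ranking and also chosen afterwards, 12 and 1 passed, again miR-29 in the CA1 (adjusted p = 0.00966 by exact rank). The meninges list genes Col3a1 and Col1a1 hold a miR-29 7mer-m8 site and stood at 2.01 and 0.835 log2 in the CA1, without passing. The site test was not run without meninges genes.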

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

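These results drew a closer look for 1 of 2 reasons: a KO effect that differed between the tissues in a test, or a signal in data that the comparisons did not use. The interaction tests were fixed before the data were examined, and the test of miR-29 sites in the meninges list was written before its result was seen. The checks of read numbers, of the ERCC, Xist and Y-linked signals, of microglia and blood and of meninges in the samples were chosen after the results were seen.

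The interaction passed for 18 genes (edgeR). By the difference in log2 fold change, CA1 less neocortex, the effect was higher in the CA1 for the complement subunits C1qc (0.71) and C1qa (0.68), the lysozyme Lyz2 (1.13), the hormone Trh (2.74), the laminin Lamb2 (0.56), Igfbp2 (1.05), Hap1 (0.58), the calcium channel Itpr3 (1.12), the Wnt antagonist Frzb (1.17), Arhgap36 (3.18) and Sh3rf2 (7.78). It was lower for 7, among them Rasgrp1 (-0.59), Arap2 (-0.47), Plxna4 (-0.55), Fbxo32 (-0.66), Shisa7 (-0.39) and Wnt1 (-8.92). With animal as a block, Sh3rf2 (edgeR adjusted p = 0.0710), Arhgap36 (edgeR adjusted p = 0.0646), Wnt1 (edgeR adjusted p = 0.0621) and Shisa7 (edgeR adjusted p = 0.0532) no longer passed. The values of Sh3rf2 and Wnt1 depend on the prior count. Sh3rf2 had 0 reads in the CA1 controls and 30 in the KO libraries, at least 16.4-fold higher in KO against a floor of 3 reads over the group. Wnt1 had a KO over control ratio of 32.5 (8.68 to 273, from 73 and 2 reads) in the neocortex and of 0.0495 (0.00122 to 0.296, from 1 and 33 reads) in the CA1, with 95% exact counting intervals that leave out the spread between animals.

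As lists, 10 had a higher mean effect in the CA1 by camera: complement and antigen presentation (0.673), activated microglia (0.697), meninges and fibroblast (1.14), reactive astrocyte (0.597), interferon response (0.54), homeostatic microglia (0.233), endothelial and pericyte (0.226), cytosolic ribosomal proteins (0.123), p53 response (0.305) and autophagy and lysosome (0.079). The 5 with a lower effect were oligodendrocyte (-0.395), CA1 pyramidal (-0.391), glutamate receptors and postsynaptic density (-0.165), immediate early genes (-0.49) and mitochondrially encoded oxidative phosphorylation (-0.271). Only the complement, reactive astrocyte and CA1 pyramidal lists also passed with an estimated correlation. With animal as a block as well they did not (camera adjusted p of 0.467, 0.472 and 0.494). That fit leaves little replication, so these values cannot show that the difference is absent.

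Outside the comparisons, the ERCC RNAs differed in relative amount between 2 sets of neocortex libraries, with an SD of the log2 ratio of 1.21 over 27 RNAs against at most 0.32 within a set. The CA1 library of the male KO animal D5133 held 21.1 CPM of Xist, 3.51% of the level in the female D5138, while the neocortex library of that animal held 0.137 CPM. The Y-linked genes of D5134, a male control, stood at 41.1% of the male median in the neocortex and at 45% in the CA1. The origin of these signals was not tested.

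Of activated microglia genes 12 of 24 rose in the neocortex and 16 of 24 in the CA1, but the list did not pass with an estimated correlation (camera adjusted p of 0.295 and 0.0902), and without D5133 the 12 became 2 while the median of all 24 went from 0.385 to 0.361. The list shares 4 of its 24 genes with other lists, and 19 had at least 1 CPM in CA1 controls, up to 1,163 CPM for Apoe. If KO samples held more microglia in an unchanged state, the homeostatic list would rise as far, but its median was 0.186 (SD 0.272, 15 genes) in the CA1 against 0.785, and -0.038 (SD 0.203) in the neocortex against 0.385. Blood left in the tissue would raise the erythroid genes Hba-a1, Hba-a2, Hbb-bs, Hbb-bt and Alas2 as far, and their median was 0.278 in the CA1 (SD 0.028 between genes), though the single-gene SE of 0.225 to 0.364 makes this a weak argument. A change of state and a larger number of activated microglia both stay open, as hypotheses that were not tested. Whether other cells in the CA1 samples, such as those carried along with meninges, raised these genes was not tested either.

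Of meninges and fibroblast genes 8 of 15 passed as higher in the CA1 and 4 without D5130, and the list did not pass with an estimated correlation (camera adjusted p = 0.104). The list has 14 of its 15 genes at 1 CPM or more in CA1 controls, up to 37.5 CPM for Igf2, and shares 4 genes with other lists. Loss of repression by miR-29 would spare members without a miR-29 7mer-m8 site, but these had a median of 1.295 (13 genes, SD 0.532), against 1.423 (SD 0.832) for the 2 with one. The listed miR-29 target Col1a2 is among the 13 and has a 6mer, and the 10 members without even a 6mer, a test added afterwards, had a median of 1.113 (SD 0.485). More meninges carried along with the KO samples and a growth of the meninges in KO animals cannot be told apart. Either would give 14 of 15 members with a log2 fold change above 0.5. This doubt extends to Col1a2, Sparc, Eln and Igf2 in the CA1. Whether the doubt extends to the miR-29 site result there was not tested. Col3a1 and Col1a1 hold a 7mer-m8 site, but the 8mer behind that result was not checked in them.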

How the results depend on the processing

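The batch term and single spike-in sets, the alternative rankings of miRNA sites, the settings other than estimated correlation, fry within a tissue, males and the block for the list tests, and the counts over other splits of the libraries were chosen after the data were seen. The other alternatives were fixed before.

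For the neocortex, DESeq2 called 487 genes higher and 435 lower against 256 and 204, and no expression filter gave 396 and 374. RLE size factors gave 256 and 204. Leaving out 1 library gave 16 to 225 higher and 3 to 205 lower, lowest without D5133. The spike-in set as a batch term gave 122 and 69, set 1 alone 10 and 1, and set 2 alone 55 and 22. No setting called a gene against its reported direction. Scaling by ERCC counts left 4 higher and 0 lower by edgeR, with 583 at an unadjusted p under 0.05. It moved the median log2 fold change of all genes to 1.06, so named genes were compared relative to that median, a choice made after signs were seen to flip. Without this step, 24 of the 27 named genes called lower had a positive value, and 0 of the 37 called higher a negative one. ERCC reads made up 0.113 to 0.268% of a KO library and 0.189 to 0.686% of a control library. The ranges overlap, but within each spike-in set every KO library lay below every control. A shift of all transcripts together stays open, since the amount of RNA and of spike-in added cannot be told apart here.

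Of the 10 ways to split the 6 neocortex libraries into 3 and 3, the real one called 460 genes and the next highest 4, and the split along the spike-in sets called 0. For lists the real split called 16 and the highest other 14. In each case 1 of the 10 splits, the real one, gave as many, a share that cannot go under 0.1. Each other split keeps 2 KO libraries together, so part of a genotype effect stays in it.

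For the CA1, DESeq2 called 507 and 417 genes against 452 and 258, and no filter gave 858 and 609. Leaving out 1 library gave 149 to 441 higher and 67 to 291 lower, and males alone gave 177 and 67. A lone KO library in these fits is assumed to vary like the controls.

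For the interaction, DESeq2 called 68 and 91 genes against 11 and 7, no filter gave 79 and 158, and leaving out 1 library gave 0 to 19 and 0 to 12. With animal as a replicate block, which pairs the tissues of 4 animals, 36 genes were higher and 78 lower, sharing 9 of the 11 and 4 of the 7. The block called 12 lists higher and 8 lower against 10 and 5 and lost the p53 response (camera adjusted p = 0.0806). The 5 genes lost include Sh3rf2, Arhgap36, Wnt1 and Shisa7, and of the 18 genes and 15 lists called without it the block changed no other call. Some other settings ended the camera calls of immediate early genes, mitochondrially encoded oxidative phosphorylation, autophagy, ribosomal proteins and homeostatic microglia.

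List calls depended on whether camera used the preset or an estimated correlation, and not only through the size of the correlation. Reactive astrocyte genes in the CA1 had an estimated correlation of 0.00772, below the preset 0.01. Their unadjusted camera p still went from 2.15e-16 to 0.00355. Camera with an estimated correlation left 0 higher and 0 lower in the neocortex, 0 and 0 in the CA1, and 2 and 1 in the interaction. Fry gave 0 and 0 in the neocortex, 9 and 2 in the CA1, and 4 and 1 in the interaction, where it was added afterwards. In the neocortex, 4 lists were lower under ERCC scaling and 4 in set 1 alone, against 7.

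The correlation of effects across genes (r 0.313, rho 0.307) was 0.447 and 0.42 for genes with at least 10 CPM, 0.151 and 0.195 with unshared animals, and 0.240 to 0.348 and 0.211 to 0.323 when 1 library was left out. For miRNA sites, 0 families passed as planned. Ranked by the difference over its SE, 7 passed in the neocortex and 1 in the CA1. With genes of at least 1 CPM in that ranking 11 and 2 passed, and on their residuals 12 and 1. With 7mer-m8 sites or the longest 3′ UTR, 0 passed.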

Other observations

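The genes in the first 2 paragraphs were picked after their values were seen. Some chemokines and receptors on the activated microglia list rose in both tissues. In the neocortex, 2 of the 24 genes on that list passed when D5133 was left out. Ccl3 rose by 2.58 (SE 0.43, edgeR adjusted p = 0.0118) in the neocortex and 2.98 (SE 0.44, edgeR adjusted p = 0.00220) in the CA1, and Ccl4 by 3.38 (SE 0.595, edgeR adjusted p = 0.0143) and 3.88 (SE 0.60, edgeR adjusted p = 0.00309). The lipid receptor Trem2 rose by 0.46 (SE 0.105, edgeR adjusted p = 0.0390) and 1.02 (SE 0.11, edgeR adjusted p = 0.000157). Clec7a, a pattern receptor, had 97 KO and 3 control reads in the CA1, a ratio of 52.9 (95% exact counting interval 17.6 to 261).

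Of glutamate receptor and postsynaptic density genes 25 of 31 were lower in the CA1, where 2 fell and 1 rose by edgeR, and 7 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00137, adjusted p = 0.312 with an estimated correlation). The vesicle protein gene Vamp1 changed by -0.35 (SE 0.066, edgeR adjusted p = 0.0176) in the neocortex and -0.29 (SE 0.068, edgeR adjusted p = 0.0285) in the CA1, while the glutamate receptor Grm2, the only member of that list to pass as higher, rose by 0.27 (SE 0.055, edgeR adjusted p = 0.0241) and 0.45 (SE 0.075, edgeR adjusted p = 0.00510). In the CA1 the glutamate transporter Slc17a6 changed by -0.83 (SE 0.13, edgeR adjusted p = 0.00714). Of host transcripts of miRNAs 2 of 13 rose in the CA1, and 2 when adjusted over the list alone, Mir124a-1hg at 0.30 (SE 0.060, edgeR adjusted p = 0.0125) and Mirg at 0.37 (SE 0.092, edgeR adjusted p = 0.0376), and 1 of 13 in the neocortex, and 5 when adjusted over the list alone, with C130071C03Rik at 0.27 (SE 0.062, edgeR adjusted p = 0.0439). As a list they had a camera adjusted p of 0.178 in the CA1 and 0.0257 in the neocortex, and 0.363 and 0.364 with an estimated correlation.

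In 3 housekeeping lists most members stood slightly below the median gene in the neocortex, though 0 passed. Of ribosomal protein genes 43 of 47 were lower (median -0.082), with 0 passing by edgeR, 3 at an unadjusted p under 0.05 and 0 by DESeq2. Of nuclear genes for oxidative phosphorylation 31 of 36 were lower (median -0.113), with 0 passing by edgeR, 14 at an unadjusted p under 0.05 and 3 by DESeq2. Of proteasome genes 30 of 31 were lower (median -0.084), with 0 passing by edgeR, 5 at an unadjusted p under 0.05 and 0 by DESeq2. Camera gave adjusted p of 0.00341, 7.61e-06 and 0.000531 with the preset and 0.778, 0.682 and 0.685 with an estimated correlation. The lean depended on the control library D5134, without which the medians were -0.011, -0.064 and -0.029, and in spike-in set 1 alone they were -0.023, -0.050 and -0.014.

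For miRNA sites in the neocortex, 0 of 20 families passed the rank test fixed beforehand (lowest adjusted p 0.293), and 0 with 7mer-m8 sites or the longest 3′ UTR. In settings chosen afterwards, with genes of at least 1 CPM ranked by the difference over its SE, 11 passed as they were and 12 on residuals from 3′ UTR length, C and G share and expression level, so taking off these trends did not end the calls, and with the spike-in set as a further term 12 passed as well. Of 10 splits of the 6 libraries 1, the real one, gave as many, but the split of D5129, D5132 and D5133 against the rest gave 11, and the share cannot go under 0.1. The tests with the spike-in sets and the splits were written before their results, and the test of trends after. The split that gave 11 keeps 2 KO libraries, D5132 and D5133, together, and its 11 families all stood higher on their side. Part of a genotype effect would stay in such a split, so its count cannot tell that effect from chance. Loss of miRNA repression in neurons stays a hypothesis here, since the splits cannot decide it.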
